A study of Homo sapiens with 8 samples.

How the data were processed

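The deposited table gave FPKM by the authors for 8 RNA-seq libraries of the gastric adenocarcinoma line AGS, with 4 columns of log2 ratios that the authors computed from those values. Per the submitters' processing notes, reads were mapped to GRCh38 (hg38) with BWA and Bowtie and quantified with Cufflinks, and the versions are not given in the sources used here. The gene annotation, the handling of reads with several locations and the number of reads per library are not given there either. Read counts were therefore not modelled, and the FPKM values were used as they stood. The authors' log2 ratios were recomputed from FPKM to within 5.00e-05 once a value of 0 was replaced by 0.01, and they were not used further.

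The table held 15739 entries, of which 178 (highest mean FPKM 0.453) had no gene name and 87 named ones had a missing value (highest FPKM 1.18). Of the 15561 named genes, 14666 symbols were found directly in GENCODE release 44 on GRCh38, 364 through an older symbol, 28 were ambiguous and 503 were not found. Coordinates in the text come from that release. Genes with a mean FPKM of at least 1 over the 8 libraries were tested, which left 11189.

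Values were analysed as log2(FPKM + 1), a scale that understates the fold change of genes near or under 1 FPKM. Each compound library was compared with its own vehicle as a matched log2 ratio, 1 library against 1, with no p-value. Each was also compared with all 4 vehicles in a linear model with 5 groups, fitted with limma 3.58.1 in R 4.3.3. The model had 3 residual degrees of freedom, and 5.07 were added by moderating the variances across genes, with a mean-variance trend. The single compound libraries were assumed to vary as the vehicles do. A gene passed when its Benjamini-Hochberg adjusted p was below 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Nothing in the labels says that the vehicles are separate cultures, so every p-value of the model with 5 groups measures only the spread between these samples, which may be technical.

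Gene lists were tested in the same model with camera, at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The second form rests on the residual degrees of freedom, 3 here and 1 with the experiment as a block, so lists could hardly pass it. Wnt targets with BAY, at an estimated correlation of −0.017, went from a camera adjusted p of 0.012 to 0.62. Failing the second form therefore does not show that correlation between genes explains a list. Of 38 lists, 34 had at least 3 measured genes. Camera sets a list against all other tested genes, so a list may pass with its own median near 0. Lists share members, so they are not separate evidence. BAX, BBC3, PMAIP1, APAF1, FAS, TNFRSF10A and TNFRSF10B are in both the p53 and the pro-apoptotic list. CYR61 and CTGF are in both the immediate early and the YAP list. Counts of list members are over all tested genes unless marked, and many are also given adjusted over the list alone. The median matched ratio of a list was placed among 10000 random lists matched on expression. For each compound the named genes were the 10 highest and 10 lowest matched ratios among genes that passed and were past 2-fold with the same sign. Where fewer than 5 passed, the 5 largest ratios outside the range of the vehicles were named instead, as values. For the 2 inhibitors together the mean ratio was ranked, and for BAY against BAY plus uridine 5 genes were named per direction. Always named were NR4A1, NR4A2, NR4A3, DHODH, CAD, UMPS, UCK2, CDKN1A, MDM2 and MYC, and up to 4 members of each list with the largest ratios in BAY and AchA. XPC, CCNG1, PERP, RPS15, RPS26, CXCL3, BOK, REG4, SERPINB2 and SPRR2D were named after their values were seen.

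The groups, contrasts, lists, filter and alternatives were chosen before the data were examined. After results were seen, 3 short lists were added (PSG family, squamous genes, and terminal oligopyrimidine mRNAs that encode no ribosomal protein). Chosen after the results as well were the list tests of BAY against AchA, those of the inhibitors with the experiment as a block, the model without the experiment of vehicle 3, and the difference of the matched ratios of BAY and BAY plus uridine.

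Titles tie each compound to 1 vehicle. Across genes, BAY, AchA and BAY plus uridine each departed from the other libraries together with the own vehicle (r = 0.47, 0.63 and 0.64). For CsnB and its vehicle r was only 0.11. A model with the experiment as a block could be fitted only with BAY and AchA as 1 class, and its results are given beside those of the 2 inhibitors. Its 1 residual degree of freedom is the difference between the matched ratios of BAY and AchA. Its p-values therefore measure how unlike the 2 compounds were and not the spread of replicates. Other alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, median-ratio scaling, quantile normalization, a robust prior, and each vehicle left out in turn.

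In simulated data with the vehicles' spread, the model of 1 library against 4 found 25.2% of genes shifted by 1 log2 unit, 98.4% of those shifted by 2 and 99.6% of those shifted by 3. False calls made up 6.91% of calls. Of 200 unshifted lists, 2.5% had a camera p below 0.05, and a simulated list of 40 genes shifted by 0.5 log2 units was found. Genes were drawn independently and without differences between experiments. In the data the estimated correlation was 0.77 for S phase genes and 0.50 for ribosomal proteins. The simulation thus does not show how many false calls correlated genes or differences between experiments would give.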

Results

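The series holds 8 RNA-seq libraries of AGS, a human gastric adenocarcinoma cell line, after 48 h of treatment. There were 4 vehicle libraries and 1 library each of BAY (5 nM) and AchA (0.75 µM), labelled inhibitors of DHODH, of BAY plus uridine (100 µM), and of CsnB (40 µM), labelled an agonist of NR4A1. DHODH encodes a mitochondrial enzyme of pyrimidine synthesis, and NR4A1 encodes a nuclear receptor. The depth of sequencing is unknown, and FPKM summed over named genes ranged from 441709 (BAY) to 510029 (CsnB). The 10 most abundant genes took 13.3% of the CsnB total and 6.99% to 8.14% of every other library.

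The 4 vehicles were not alike. Between pairs of vehicles 1, 2 and 4, from 74 to 248 genes differed by at least 2-fold, and pairs with vehicle 3 differed in 539 to 862. Vehicle 3 and BAY plus uridine, which the titles pair, departed from the mean of vehicles 1, 2 and 4 together (r = 0.90 across genes). In vehicle 3, SERPINB2 stood at 109 FPKM and SPRR2D at 57.9, against 5.96 and 0.72 in vehicle 1, and INHBE stood at 38.9 against 2.12. S phase genes had a median log2 deviation of −0.74 in vehicle 3, immediate early genes 0.85 and integrated stress response genes 0.76. These and later list medians for vehicle 3 are deviations from the mean of vehicles 1, 2 and 4.

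**Figure D1:**
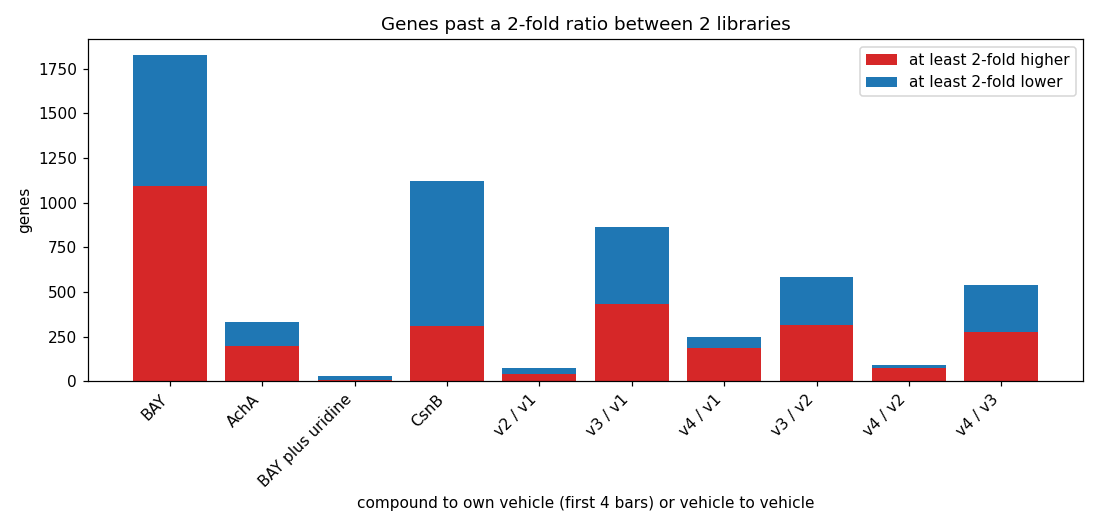
Genes past a 2-fold ratio between 2 libraries. BAY had 1826, AchA 331, BAY plus uridine 28 and CsnB 1119 against their own vehicles, and pairs of vehicles had 74 to 862.

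The first question was which genes moved with the DHODH inhibitor BAY. GAST, the gene for the stomach hormone gastrin, rose from 0.805 ± 0.310 FPKM (mean ± SD, n = 4 vehicles) to 158 (log2 6.47 ± 0.28 (SE), limma adjusted p = 9.9e-05). NPPB, which encodes a natriuretic peptide, rose to 150 FPKM from 1.37 ± 0.695, and the carboxypeptidase gene CPA4 to 52.1 from 0.318 ± 0.136. EEF1A1, the gene for a translation elongation factor, fell from 2358 ± 303 to 247 FPKM (log2 −3.24 ± 0.28, adjusted p = 6.0e-04). ASNS, which encodes asparagine synthetase, fell from 389 ± 163 to 19.0 FPKM (log2 −4.14 ± 0.60, adjusted p = 0.0043). GAST lies on GRCh38 chromosome 17 from 41712331 to 41715969, EEF1A1 on chromosome 6 from 73489308 to 73525587 and ASNS on chromosome 7 from 97851677 to 97872542.

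NR4A1 (chromosome 12, 52022832 to 52059507) rose with BAY to 111 FPKM from 18.1 ± 5.68 (n = 4), log2 2.59 ± 0.34, limma adjusted p = 0.0031. Against its own vehicle (15.5 FPKM) that was 7.15-fold. The related NR4A2 and NR4A3 were too low to test, at 1.99 and 0.62 FPKM with BAY against 0.67 and 0.11 in its vehicle. Of the pyrimidine genes, UMPS, which encodes the enzyme that makes UMP, rose to 13.7 FPKM from 5.97 ± 1.53 (log2 1.11 ± 0.32, adjusted p = 0.046). That call was lost without vehicle 2 (adjusted p = 0.059) or without vehicle 4 (adjusted p = 0.11). DHODH was at 3.48 FPKM against 4.93 ± 1.06 (adjusted p = 0.37), CAD at 18.7 against 20.3 ± 2.94 (adjusted p = 0.81) and the uridine kinase gene UCK2 at 16.5 against 20 ± 3.78 (adjusted p = 0.58). MYC, which encodes a transcription factor of growth, was at 42.4 FPKM against 72.4 ± 12.4 (adjusted p = 0.096).

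**Figure D2:**
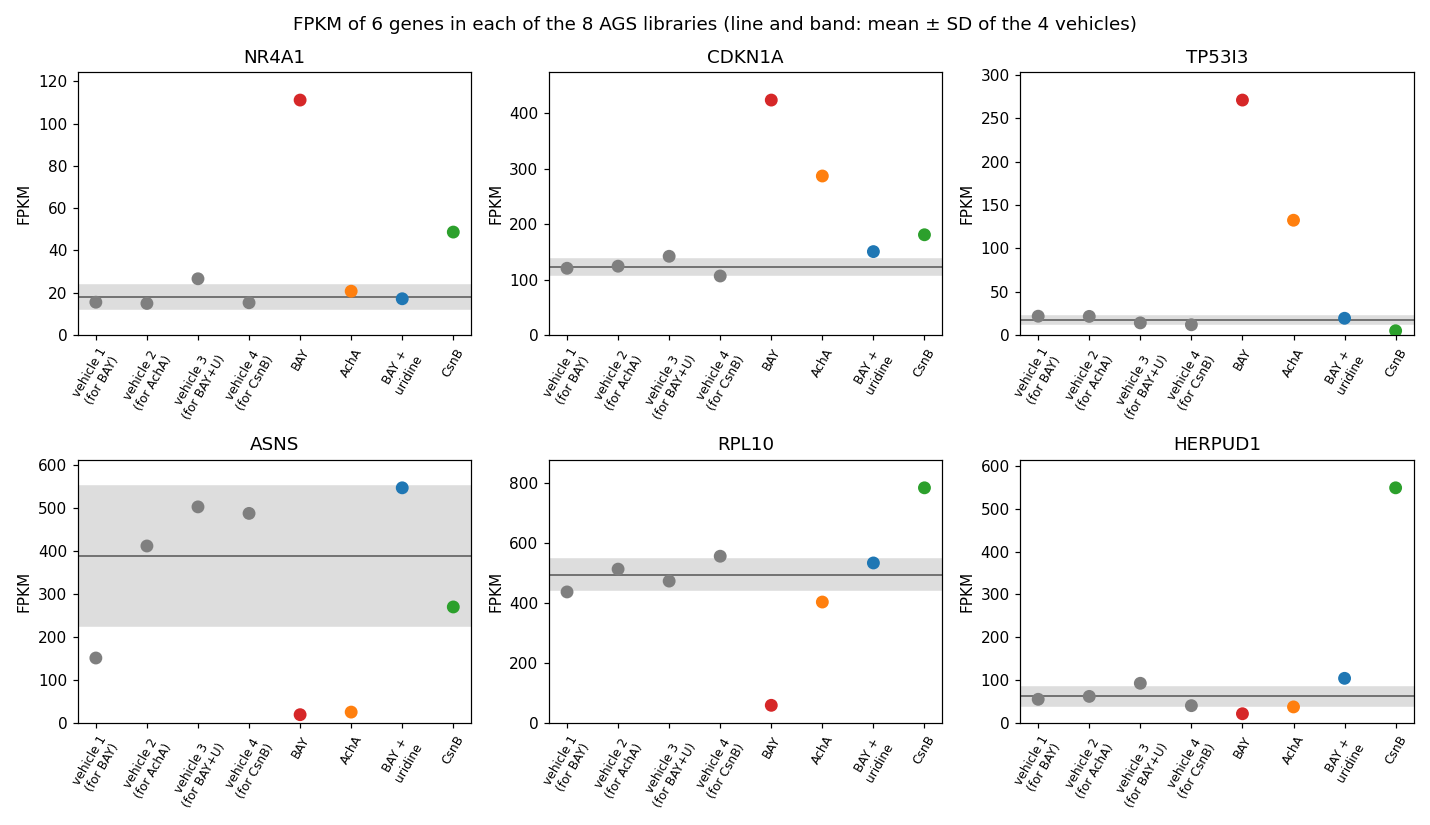
FPKM of 6 genes in the 8 libraries, with the mean and SD of the 4 vehicles. NR4A1 reached 111 with BAY and 48.7 with CsnB, and ASNS fell to 19.0 with BAY and stood at 25 with AchA.

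Of 39 measured p53 targets, 26 rose and 1 fell with BAY (30 and 1 adjusted over the list alone), with a median log2 change of 1.33 (camera adjusted p = 4.8e-10, and adjusted p = 0.62 with an estimated correlation). TP53I3 went from 17.3 ± 5.10 to 271 FPKM, and CD82 from 3.25 ± 0.746 to 31.8. CDKN1A, whose product p21 arrests the cell cycle, rose from 123 ± 14.6 to 424 (log2 1.78 ± 0.25, limma adjusted p = 0.0041). MDM2, whose product degrades p53, rose from 27.9 ± 8.76 to 96.4. XPC was the 1 that fell, from 16.5 ± 1.49 to 7.18 FPKM. CCNG1 and PERP did not pass, at 108 and 165 FPKM.

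All 74 ribosomal protein genes were measured, and 65 fell and 0 rose with BAY (72 fell adjusted over the list alone). Their median log2 change was −1.64 (camera adjusted p = 2.7e-39, and adjusted p = 0.62 with an estimated correlation). RPL10 went from 494 ± 51.3 to 58.3 FPKM, RPLP0 from 1619 ± 189 to 233 and RPL10A from 670 ± 107 to 96.4. RPS15 and RPS26 did not pass, at 504 and 97.0 FPKM against 698 ± 114 and 133 ± 16. EEF1D, another elongation factor gene, fell from 227 ± 14.5 to 31.9 (log2 −2.79 ± 0.23).

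Among 32 integrated stress response genes, many of them for amino acid synthesis and uptake, 18 fell and 2 rose with BAY (20 and 2 adjusted over the list alone). The median log2 change was −1.51 (camera adjusted p = 4.8e-09, and adjusted p = 0.85 with an estimated correlation) and −0.96 against the own vehicle. CTH fell from 37.5 ± 27.8 to 1.63 FPKM, the cystine transporter gene SLC7A11 from 19.0 ± 7.88 to 1.06 and PSAT1 from 341 ± 105 to 44.7. CBS and ATF3 were the 2 that rose, to 4.40 and 167 FPKM from 0.425 ± 0.153 and 22.5 ± 12.4. Vehicle 3 held 77.5 FPKM of CTH and vehicle 1 held 14, and ASNS was lowest in vehicle 1, at 151.

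Immediate early genes moved up with BAY, 11 of 26 rising and 0 falling (12 and 1 adjusted over the list alone, camera adjusted p = 0.0053, and adjusted p = 0.85 with an estimated correlation). CYR61 reached 117 FPKM from 8.62 ± 3.40, and CTGF 74.8 from 11.6 ± 5.86, and both are YAP targets as well. Of 12 YAP targets 5 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.85 with an estimated correlation), AXL going from 1.66 ± 0.612 to 39.5 FPKM. Of 16 NF-kB genes 11 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.76 with an estimated correlation). TNFAIP3 went from 5.85 ± 1.34 to 24.1 and LIF from 11 ± 1.16 to 47.3, while CXCL3 fell from 4.90 ± 1.36 to 0.97. Without vehicle 1 the NF-kB list no longer passed (adjusted p = 0.051). Vehicle 3 alone had medians of 0.85 for the immediate early list and 0.73 for the YAP list.

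Of 7 fatty acid synthesis genes 4 fell and 0 rose with BAY, the same number adjusted over the list alone (camera adjusted p = 0.0098, and adjusted p = 0.76 with an estimated correlation). The desaturase gene SCD went from 285 ± 34.4 to 66.6 FPKM and SREBF1 from 42.7 ± 8.43 to 17. Of 13 Wnt targets 2 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.62 with an estimated correlation), AXIN2 from 117 ± 29.3 to 42.5 FPKM and RNF43 from 59.7 ± 16.8 to 23.2. Pro-apoptotic genes did not pass as a list (camera adjusted p = 0.057), yet 11 of 26 rose and 1 fell. The death receptor gene FAS, also in the p53 list, rose from 3.08 ± 0.732 to 20.9 FPKM, and BOK fell from 25.4 ± 1.86 to 7.93.

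Over all genes, 2161 of 11189 passed with BAY (limma, Benjamini-Hochberg), 1304 higher and 857 lower, and without vehicle 3 the count was 3688. It was 2058, 1265 and 1054 without vehicle 1, 2 or 4. The median log2 change of all tested genes was 0.16, and with median-ratio scaling 47.9% of the genes that passed were higher instead of 60.3%. RGS2 (34 FPKM), FAM84A (21.1), CLTRN (28.4) and TUBA4A (45.2) rose as well, and ST6GALNAC3 (4.3), SLC6A9 (1.27), BMP4 (1.65), PCK2 (6.67) and RPL23 (147) fell. All 20 genes picked by size kept their calls under every alternative. Among them were KRTAP3-1, KRTAP2-3 and LGALS7B, which have close paralogs, so which copy was read is uncertain, at 85.9, 23.4 and 48.7 FPKM with BAY.

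The second question was which genes moved with the other labelled DHODH inhibitor, AchA. TP53I3 (chromosome 2, 24077433 to 24085861), a p53 target, rose to 132 FPKM from 17.3 ± 5.10 (n = 4), log2 2.91 ± 0.36 (SE), limma adjusted p = 0.028. APLP1 rose to 18.4 FPKM from 1.69 ± 0.351 (adjusted p = 0.020), NECTIN4 to 24.5 from 4.27 ± 0.451 and CRIP2 to 54.8 from 10.6 ± 1.30. SLC7A11 fell to 0.93 FPKM from 19.0 ± 7.88 (log2 −3.30 ± 0.41, adjusted p = 0.029), and the glycine transporter gene SLC6A9 fell to 4.18 from 26.0 ± 4.97. CHAC1, which encodes an enzyme that degrades glutathione, fell to 23.8 FPKM from 128 ± 33.1 (adjusted p = 0.044).

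Other genes that rose with AchA were CPA4 (5.46 FPKM from 0.318 ± 0.136), CBS (6.01 from 0.425 ± 0.153), EBI3 (7.18 from 0.603 ± 0.107), TMEM249 (9.06 from 0.690 ± 0.149) and GGT6 (10.4 from 1.30 ± 0.415). JDP2, which encodes a repressor of AP-1 genes, fell to 5.77 FPKM from 22.6 ± 0.678. ASNS was at 25 FPKM against 389 ± 163 (limma adjusted p = 0.083), DDIT4 at 14.5 against 231 ± 145 (adjusted p = 0.079) and CTH at 2.10 against 37.5 ± 27.8 (adjusted p = 0.19). INHBE was at 0.12 FPKM against 13.7 ± 17, a mean raised by 38.9 in vehicle 3. CDKN1A was at 287 FPKM against 123 ± 14.6 (adjusted p = 0.19), and NR4A1 at 20.7 against 18.1 ± 5.68 (log2 0.23 ± 0.34, adjusted p = 0.80). DHODH stood at 5.83 FPKM, UMPS at 7.45, CAD at 22.4, UCK2 at 23.9 and MYC at 76.2, and none of these passed.

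As lists, 32 integrated stress response genes moved down with AchA, 2 falling and 1 rising over all genes and 20 falling and 1 rising adjusted over the list alone. Their median was −1.34 (camera adjusted p = 5.2e-17, and adjusted p = 0.83 with an estimated correlation). Of 39 p53 targets 1 rose over all genes and 22 rose adjusted over the list alone, with a median of 0.83 (camera adjusted p = 2.4e-15, and adjusted p = 0.59 with an estimated correlation). FDXR was at 96.2 FPKM against 19.7 ± 5.15 and CD82 at 12.7 against 3.25 ± 0.746. The 74 ribosomal proteins had a median of 0.05, and RPL10 was at 402 FPKM against 494 ± 51.3.

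The 49 oxidative phosphorylation genes had a median log2 change of 0.47 with AchA, with 0 passing singly (camera adjusted p = 8.7e-09, and adjusted p = 0.83 with an estimated correlation). Pro-apoptotic genes (26) had a median of 0.39, 3 rising adjusted over the list alone (camera adjusted p = 0.0087, and adjusted p = 0.59 with an estimated correlation). S phase genes (48), histones (9) and deoxynucleotide synthesis genes (9) passed too, with medians of 0.35, 0.59 and 0.52 and camera adjusted p of 0.035, 0.044 and 0.047 (adjusted p = 0.87, 0.83 and 0.83 with an estimated correlation). Vehicle 3 had medians of −0.74, −0.33 and −0.46 for the same 3 lists, and none of the 3 passed without vehicle 3 or without vehicle 4. Against the own vehicle the S phase median was 0.02, and −0.02 with median-ratio scaling.

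In all, 19 genes passed with AchA (limma, Benjamini-Hochberg), 15 higher and 4 lower, and without vehicle 3 the count was 62. Without vehicle 4 it was 0, the named genes then having adjusted p from 0.14 to 0.22, and a pseudocount of 0.1 left 10. CHAC1 also lost its call without vehicle 1 (adjusted p = 0.081) or 2 (adjusted p = 0.059), as did JDP2.

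The next question was what the 2 DHODH inhibitors shared. GAST averaged a log2 rise of 4.27 ± 0.22 (SE) over the 2 (limma adjusted p = 2.3e-04), CPA4 3.82 ± 0.19, APLP1 3.37 ± 0.20 and TP53I3 3.42 ± 0.28. AXL, which encodes a receptor kinase, rose on average, at 39.5 FPKM with BAY and 10.8 with AchA against 1.66 ± 0.612 (n = 4). It did not pass with AchA alone. ASNS fell on average (log2 −3.95 ± 0.47, limma adjusted p = 0.0038), at 19.0 FPKM with BAY and 25 with AchA against 389 ± 163. Lower on average too were SLC7A11 (1.06 and 0.93), CTH (1.63 and 2.10) and PCK2 (6.67 and 22.7 against 134 ± 57.0). With AchA alone ASNS, CTH and PCK2 did not pass. CDKN1A rose by 1.50 ± 0.20 (adjusted p = 0.0051), and MDM2 by 1.32 ± 0.29 (adjusted p = 0.032). NR4A1 also passed on average (log2 1.41 ± 0.26, adjusted p = 0.019), though it was at 111 FPKM with BAY and 20.7 with AchA.

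DDIT4, which encodes an inhibitor of mTORC1, fell on average, at 26.8 FPKM with BAY and 14.5 with AchA. So did SLC1A4 (1.25 and 2.83), PSAT1 (44.7 and 77) and JDP2 (3.06 and 5.77). DDIT4, SLC1A4 and PSAT1 did not pass with AchA alone. NPPB rose on average, at 150 FPKM with BAY and 10.0 with AchA, as did CLTRN (28.4 and 2.74), TUBA4A (45.2 and 5.06) and KRTAP3-1 (85.9 and 2.65). These 4 averages were carried mainly by BAY. LGALS7B rose on average to 48.7 and 24.9 FPKM and UNC93A fell to 0.63 and 1.06, and both lost the call without vehicle 4 (adjusted p = 0.058 and 0.11). With the experiment as a block, NPPB, CPA4, APLP1, LGALS7B, AXL and TP53I3 and all 10 that fell still passed. GAST, KRTAP3-1, CLTRN and TUBA4A did not then pass (limma adjusted p = 0.091, 0.13, 0.093 and 0.11), nor did CDKN1A (0.085), MDM2 (0.15) or NR4A1 (0.18). Their log2 changes in that fit were 4.28 for GAST, 3.38 for KRTAP3-1, 3.01 for CLTRN and 2.80 for TUBA4A. Those of CDKN1A, MDM2 and NR4A1 were 1.50, 0.97 and 1.60. The spread in that fit is the difference between the BAY and AchA ratios, so a gene that moved unequally with the 2 has a larger spread there. Failing it does not show a difference between experiments.

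Ribosomal proteins averaged −0.80 over the inhibitors, 36 falling (59 adjusted over the list alone, camera adjusted p = 1.1e-27, and adjusted p = 0.80 with an estimated correlation), and that average joins −1.64 with BAY to 0.05 with AchA. RPL10 fell on average, at 58.3 and 402 FPKM. Of the p53 targets 25 rose and 0 fell (30 and 1 adjusted over the list alone, camera adjusted p = 1.2e-13, and adjusted p = 0.69 with an estimated correlation). Of the integrated stress response genes 19 fell and 2 rose (24 and 2 adjusted over the list alone, camera adjusted p = 1.2e-13, and adjusted p = 0.83 with an estimated correlation). With the experiment as a block these 3 lists passed at camera adjusted p of 7.2e-14, 3.2e-17 and 5.2e-18. Pro-apoptotic genes (5 rising, 1 falling), fatty acid synthesis genes (2 falling), Wnt targets and YAP targets (3 rising) passed both with the block and without it. Without it their adjusted p were 0.017, 0.020, 0.035 and 0.031, and none of the 34 lists passed with an estimated correlation (adjusted p of at least 0.69). The last 3 were carried by BAY, with medians of −0.91 with BAY and −0.19 with AchA for fatty acid synthesis, −0.67 and −0.13 for Wnt targets and 1.32 and 0.03 for YAP targets. The Wnt list was lost without vehicle 2 or 4 (adjusted p up to 0.059), and the YAP list without vehicle 1 or 4 (up to 0.061).

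S phase and oxidative phosphorylation genes passed only without the block (camera adjusted p = 0.020 and 0.050, then 0.61 and 0.084). Immediate early genes, endoplasmic reticulum chaperones and mesenchymal genes passed only with it (3.2e-04, 0.0042 and 0.016). The block fit left 1 residual degree of freedom, and with an estimated correlation 0 lists passed in it (adjusted p of at least 0.89). Without the block, S phase genes were lost when vehicle 3 or 4 was left out (adjusted p up to 0.10). Oxidative phosphorylation genes were lost with median-ratio scaling and without vehicle 1, 3 or 4 (up to 0.080).

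Over all genes, 966 passed for the average of BAY and AchA (limma, Benjamini-Hochberg), 594 higher and 372 lower, and 46 with the experiment as a block, 45 of them shared. Without vehicle 3 it was 2185, without vehicle 2 426 and without vehicle 4 276, and with BAY and AchA as 1 class 77. The share that was higher went from 61.5% to 49.3% with median-ratio scaling. Past 2-fold with both compounds were 132 of the genes that rose and 51 of those that fell.

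All 19 genes that passed with AchA passed with BAY in the same direction, TP53I3 and SLC7A11 among them, 15 higher and 4 lower, where independent lists would share 1.75 and 0.306. The vehicles are shared, and 50 simulations of unchanged libraries with independent genes gave 0.04 joint calls on average. Neither compound changed any gene there, so this cannot show how much shared vehicles add to the overlap. With vehicles 1 and 3 for BAY and 2 and 4 for AchA, 74 genes passed in both, and all 19 kept 1 sign. Matched ratios, each to its own vehicle, had r = 0.49 across genes (rho = 0.44), with 148 genes past 2-fold higher in both, 61 lower in both and 1 opposite. Pairs of vehicles gave r of 0.01 to 0.27 in size, but each pair joins vehicles titled for different compounds, so they are no like background. Genes are not independent replicates.

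**Figure D3:**
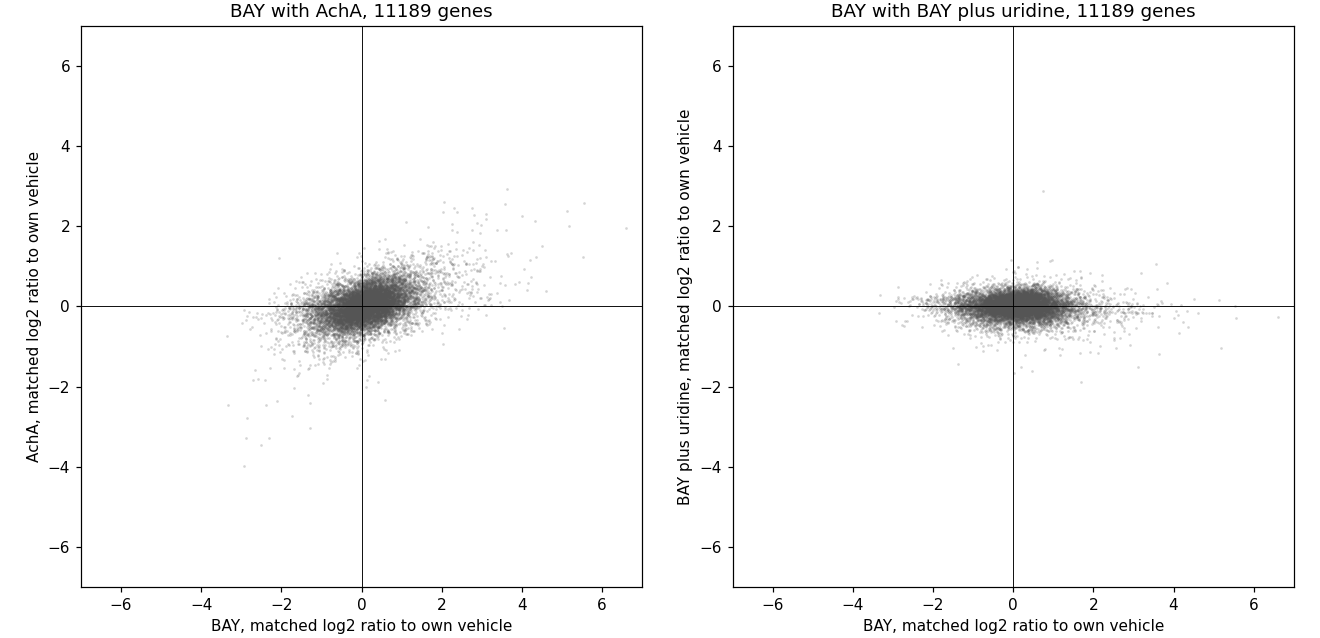
Matched log2 ratios of 11189 genes, BAY with AchA (r = 0.49) and BAY with BAY plus uridine (r = −0.04).

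A further question was where BAY and AchA differed. NR4A1 was 111 FPKM with BAY and 20.7 with AchA (log2 difference 2.37 ± 0.43 (SE), 95% interval 1.37 to 3.36, limma adjusted p = 0.035). GAST was 158 and 6.47 FPKM (difference 4.41 ± 0.35, adjusted p = 0.0045), NPPB 150 and 10.0 (3.77 ± 0.46, adjusted p = 0.0098) and KRTAP3-1 85.9 and 2.65. CDKN1A did not differ by the test (0.56, 95% interval −0.17 to 1.30, adjusted p = 0.35), nor did MDM2 (0.96, −0.13 to 2.04) or UMPS (0.80, −0.13 to 1.73).

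Ribosomal proteins were lower with BAY than AchA, 39 of 74 singly and 70 adjusted over the list alone (median −1.64, camera adjusted p = 2.6e-47, and adjusted p = 0.78 with an estimated correlation). Higher with BAY were immediate early genes (median 1.04, 2 singly and 8 adjusted over the list alone), NF-kB genes (1.02, 3 and 10), YAP targets (1.07, 0 and 4) and p53 targets (0.43, 4 and 10). Lower were oxidative phosphorylation genes (−0.41), fatty acid synthesis genes (−0.46) and Wnt targets (−0.47). Camera adjusted p for these 7 ran from 9.3e-05 to 0.037, and none passed with an estimated correlation. CYR61 was at 117 FPKM with BAY and 24.8 with AchA, and CD82 at 31.8 and 12.7. Of 11189 genes 354 passed (limma, Benjamini-Hochberg), and 1787 without vehicle 3, 144 without vehicle 2 and 42 without vehicle 4. The higher share went from 60.2% to 47.9% with median-ratio scaling.

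The question for BAY plus uridine was whether any gene left the vehicle level when uridine, which cells can salvage into UMP, was given with BAY. NR4A1 was at 17.2 FPKM, against 26.6 in its own vehicle and 18.1 ± 5.68 over the 4 (log2 −0.03 ± 0.34 (SE), limma adjusted p = 0.98). GAST was at 0.23 FPKM, CPA4 at 0.37, CDKN1A at 151 against 142 in the own vehicle, MDM2 at 23.5 against 22.7, ASNS at 548 against 503 and RPL10 at 533 against 472. DHODH was at 4.38 FPKM, UMPS at 5.00, CAD at 16.7, UCK2 at 14.2 and MYC at 58.1. No gene passed (limma, Benjamini-Hochberg, 0 of 11189), with 509 at unadjusted p below 0.05, and 818 passed without vehicle 3.

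Against the own vehicle, 6 genes were past 2-fold higher with BAY plus uridine and 22 lower. Pairs of vehicles differed in 74 to 862, but each pair joins vehicles titled for different compounds. Those counts include differences between experiments, so they give no background for a matched ratio. Without vehicle 3, BAY plus uridine is compared only with vehicles of other experiments, so genes passing then may reflect that difference. Among genes outside the range of the 4 vehicles, those named for high ratios were SERF1A (6.34 FPKM against 0), GTF2H2C_2 (12.9 against 5.28) and HIST2H4A (2.12 against 0.57), members of duplicated families whose reads are hard to place, with ARRDC3 (6.50 against 2.38) and CSTA (2.69 against 0.78). Named for low ratios were PSG2 (4.15 FPKM against 18.1), SIK1 (1.16 against 5.81), PSG1 (2.27 against 9.06), PSG11 (9.25 against 28.2) and PRF1 (7.41 against 21.7). The PSG genes belong to a family of near-identical pregnancy glycoprotein genes on chromosome 19 whose members are uncertain.

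As lists, 9 passed with BAY plus uridine against the 4 vehicles, and vehicle 3 moved with each of them. Integrated stress response genes had a median of 0.68 (camera adjusted p = 1.5e-12, and adjusted p = 0.65 with an estimated correlation), 0.76 in vehicle 3 alone and 0.17 against the own vehicle. S phase genes had −0.59 (camera adjusted p = 1.2e-08), −0.74 in vehicle 3 and 0.00 against it. Cholesterol synthesis had −0.40, heat shock genes −0.72, gastrointestinal differentiation −0.56 and fatty acid synthesis −0.36, and vehicle 3 had −0.54, −0.71, −0.48 and −0.29. YAP targets had 0.60, immediate early genes 0.43 and anti-apoptotic genes 0.46, and vehicle 3 had 0.73, 0.85 and 0.64. For S phase, immediate early and YAP genes the median against the own vehicle had the other sign (0.00, −0.09 and −0.04), though for S phase genes it was −0.01 with median-ratio scaling. None passed with an estimated correlation. Taken against vehicles 1, 2 and 4 as well, BAY plus uridine had 0.91 for stress response, −0.78 for S phase and −0.52 for cholesterol synthesis genes. By that reference heat shock genes had −0.87, gastrointestinal differentiation −0.68 and fatty acid synthesis −0.40. YAP targets then had 0.82, immediate early genes 0.58 and anti-apoptotic genes 0.61. CTH, a stress response gene, was at 88.5 FPKM against 77.5 in vehicle 3 and 14 in vehicle 1.

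The question of whether uridine undid the response to BAY was asked directly. GAST was 158 FPKM with BAY and 0.23 with BAY plus uridine (log2 difference 7.01 ± 0.35 (SE), limma adjusted p = 4.4e-04), CPA4 52.1 and 0.37 and NPPB 150 and 1.15. NR4A1 was 111 and 17.2 FPKM (2.63 ± 0.43, adjusted p = 0.011), CDKN1A 424 and 151 (1.49 ± 0.32, adjusted p = 0.024) and MDM2 96.4 and 23.5 (1.99 ± 0.47, adjusted p = 0.032). ASNS was 19.0 with BAY and 548 with uridine added (−4.78 ± 0.76, adjusted p = 0.010), CTH 1.63 and 88.5 and PCK2 6.67 and 218. INHBE and UNC93A, at 0.29 and 0.63 FPKM with BAY and 37.6 and 46.9 with uridine, lost the call without vehicle 4 (adjusted p = 0.098 and 0.079). UMPS was 13.7 and 5.00 (adjusted p = 0.067). KRTAP3-1 and KRTAP2-3 were 85.9 and 23.4 FPKM with BAY and 0.09 and 0 with uridine. The own vehicles differed too, INHBE at 2.12 FPKM in vehicle 1 and 38.9 in vehicle 3, and UNC93A at 4.39 and 48.8. Relative to the own vehicle, INHBE was 0.14-fold with BAY and 0.97-fold with uridine added, and UNC93A 0.14 and 0.96. By that measure ASNS was 0.13 and 1.09, CTH 0.12 and 1.14 and PCK2 0.12 and 1.17. For these genes the direct differences thus include that between experiments.

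Ribosomal proteins were lower with BAY than with BAY plus uridine, 57 of 74 singly and 64 adjusted over the list alone (median −1.71, camera adjusted p = 1.0e-34). Of the integrated stress response genes 19 were lower and 1 higher (26 and 2 adjusted over the list alone, median −2.22), and of the p53 targets 23 higher and 1 lower (25 and 1, median 1.47). S phase genes (10 higher, median 1.17), heat shock genes (6 higher, 1.46) and cholesterol synthesis genes (2 higher, 0.76) also passed, at camera adjusted p of 1.1e-04, 0.024 and 0.046, the last of them lost without vehicle 4 (adjusted p = 0.053). Vehicle 3 alone stood at −0.74, −0.71 and −0.54 for those 3 lists and at 0.76 for the stress response list, so these differences include that between experiments. Against their own vehicles, stress response genes had medians of −0.96 with BAY and 0.17 with BAY plus uridine, ribosomal proteins −1.53 and 0.19, and p53 targets 1.34 and −0.02. The other 3 lists were close together by that measure, S phase genes at 0.19 and 0.00, heat shock genes at 0.18 and −0.08 and cholesterol synthesis genes at 0.02 and −0.16. None of the 6 passed with an estimated correlation (adjusted p at least 0.92). PCNA, an S phase gene, was 513 FPKM with BAY and 101 with uridine, against 234 in vehicle 1 and 93.8 in vehicle 3.

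Of all genes, 1626 passed between BAY and BAY plus uridine (limma, Benjamini-Hochberg), 1024 higher and 602 lower with BAY, and without vehicle 3 4154, without vehicle 2 984 and without vehicle 4 562. With median-ratio scaling the higher share was 50% instead of 63.0%. Each taken to its own vehicle, the difference of the 2 ratios was past 2-fold in 1226 genes higher with BAY and 768 lower.

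Among 331 genes past 2-fold with AchA, ASNS and TP53I3 included, the BAY ratio had the same sign as AchA in 91.8%, and BAY plus uridine had the sign of BAY in 41.1% (136, 95% interval 35.7 to 46.6). The median size of the ratio was 1.34 with BAY and 0.19 with BAY plus uridine, and the slope of the latter on the former was −0.042 (SE 0.0101). The interval and SE treat genes as independent and cover no variation between cultures. ASNS had ratios of −2.93 with BAY and 0.12 with uridine, and TP53I3 3.58 and 0.44. Against the mean of the 4 vehicles, 442 genes were past 2-fold with AchA, and for these the slope was −0.16 and the share 26.7%. BAY plus uridine then carries the departure it shares with vehicle 3, so these values do not show that uridine reversed the response.

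The question for CsnB was which genes an NR4A1 agonist moved, and whether they were those of BAY. HERPUD1 (chromosome 16, 56932142 to 56944864), a gene of endoplasmic reticulum stress, rose to 549 FPKM from 62.3 ± 22.0 (n = 4), log2 3.18 ± 0.40 (SE), limma adjusted p = 0.033. FTL, the ferritin light chain gene, rose to 21402 FPKM from 4836 ± 451, and SQSTM1, for an autophagy adaptor, to 892 from 134 ± 37.0. INSIG1 and MSMO1, of sterol metabolism, rose to 115 and 189 FPKM from 13.4 ± 4.82 and 30.0 ± 5.63. CLDN2, a tight junction gene, fell to 0.28 FPKM from 10.4 ± 2.70 (log2 −3.12 ± 0.32, adjusted p = 0.033), and PLA2G2A, for a secreted phospholipase, to 98.0 from 623 ± 124. NR4A1 itself was at 48.7 FPKM, 3.19-fold its own vehicle (log2 1.42 ± 0.34, adjusted p = 0.096).

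Also higher were ARRDC3 (25.7 FPKM from 1.28 ± 0.780), ZNF165 (66.0 from 9.23 ± 2.38), LYPD3 (30.4 from 3.93 ± 1.41), RELB (21.7 from 3.76 ± 1.07) and ARF4 (532 from 127 ± 11.5). EGLN3, for an oxygen-sensing hydroxylase, fell to 9.5 FPKM from 48.8 ± 7.63, SYTL2 to 3.03 from 19.4 ± 3.13, TAF15 to 19.5 from 77.3 ± 9.43, PPP1R10 to 4.14 from 19.3 ± 3.15 and KRCC1 to 0.84 from 5.98 ± 0.398. PSG2, PSG11 and PSG1, whose near-identical sequences leave the copy uncertain, fell to 0.48, 1.72 and 0.39 FPKM. CDKN1A was at 181 FPKM (limma adjusted p = 0.25), MDM2 at 12.3, MYC at 95.1, CAD at 16.3 and UCK2 at 16.8. DHODH was at 1.82 against 4.93 ± 1.06 (adjusted p = 0.12) and UMPS at 3.17 against 5.97 ± 1.53 (adjusted p = 0.24).

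Of 22 chaperones of the endoplasmic reticulum 1 rose with CsnB and 9 rose adjusted over the list alone (median 0.88, camera adjusted p = 3.8e-12, and adjusted p = 0.52 with an estimated correlation). PDIA4 was at 601 FPKM against 221 ± 77. Oxidative stress genes (21) had 1 and 5 rising (median 0.71, camera adjusted p = 1.6e-09, and adjusted p = 0.52 with an estimated correlation), SRXN1 at 133 FPKM against 32.9 ± 8.26. Cholesterol synthesis genes (25) had 2 rising and 9 adjusted over the list alone (median 0.72, camera adjusted p = 1.6e-09, and adjusted p = 0.57 with an estimated correlation). Ribosomal proteins moved up (median 0.35, 0 singly, camera adjusted p = 6.3e-14, and adjusted p = 0.60 with an estimated correlation), RPL10 standing at 783 FPKM. Their median against the own vehicle was 0.21, and 0.01 with quantile normalization. Immediate early genes (26) had a median of 0.73 (1 rising adjusted over the list alone, camera adjusted p = 2.1e-09, and adjusted p = 0.57 with an estimated correlation), and vehicle 3 had 0.85.

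S phase genes (48) moved down with CsnB, median −0.89 with 0 passing singly (camera adjusted p = 4.5e-05, and adjusted p = 0.76 with an estimated correlation), and vehicle 3 had −0.74. CCNE2 was at 1.53 FPKM against 7.17 ± 3.07, and PCNA at 63.7 against 179 ± 70.5. Gastrointestinal differentiation genes (13) had a median of −0.77, 6 falling adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.56 with an estimated correlation), REG4 standing at 13.1 FPKM against 145 ± 69.1. Without vehicle 4 that list no longer passed (adjusted p = 0.059), and vehicle 3 had −0.48. NF-kB genes (6 up and 2 down adjusted over the list alone, median 0.37) and metallothioneins (2 up adjusted over the list alone, 0.87) passed. Their camera adjusted p were 3.5e-04 and 0.0046 (adjusted p = 0.56 and 0.52 with an estimated correlation). RELB and MT2A reached 21.7 and 166 FPKM.

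Mitotic genes (median 0.08), deoxynucleotide synthesis genes (−0.49, 4 down adjusted over the list alone), integrated stress response genes (0.06) and autophagy genes (0.08) also passed with CsnB. The median of all tested genes was −0.20, so the lists at 0.06 and 0.08 passed relative to the other genes and did not themselves clearly rise. Their camera adjusted p were 0.0035, 0.031, 0.031 and 0.050 (adjusted p = 0.76, 0.68, 0.84 and 0.56 with an estimated correlation). The last 2 lists lost the call without vehicle 1, without vehicle 4 or with median-ratio scaling (adjusted p up to 0.39 and 0.093). DDIT4 stood at 374 FPKM with CsnB and MAP1LC3B at 67.9, against 231 ± 145 and 39.4 ± 20.6.

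Of 11189 genes 21 passed with CsnB (limma, Benjamini-Hochberg), 10 higher and 11 lower, and without vehicle 3 the count was 2393, 590 higher and 1803 lower. Without vehicle 1 or 4, with quantile normalization or with no filter it was 0, so HERPUD1 had adjusted p = 0.081 and 0.15 without those vehicles, and with a pseudocount of 0.1 it was 134. The median log2 change of all genes was −0.20 (−0.22 to the own vehicle), and scaling took the higher share from 47.6% to 60.9%, and that of matched 2-fold genes from 27.7% to 54.4%.

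Matched ratios of CsnB and BAY had r = 0.16 across genes, with 114 genes past 2-fold higher in both, 110 lower in both and 90 opposite. Independent lists would share 30.4 higher and 52.8 lower, and the number expected to be opposite was not computed. Pairs of vehicles had r of 0.01 to 0.27 in size, but each pair joins vehicles titled for different compounds. They are thus no like background for these ratios. NR4A1 and RELB were higher with both, CLDN2 lower with both (0.87 and 0.28 FPKM). SYTL2 was 47.3 FPKM with BAY and 3.03 with CsnB, PSG2 66.3 and 0.48 and EEF1A1 247 and 3596. CsnB and AchA had r = 0.04, AchA and BAY plus uridine −0.05, and CsnB and BAY plus uridine 0.00.

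**Figure D4:**
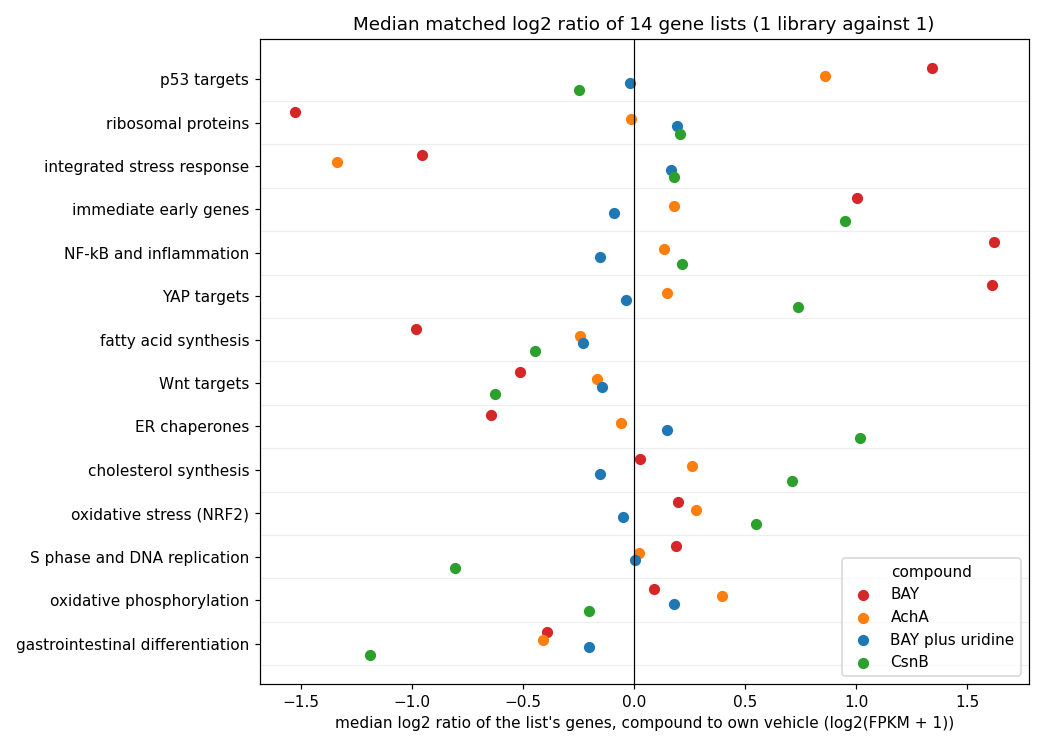
Median matched log2 ratio of 14 gene lists in each compound library. Ribosomal proteins stood at −1.53 with BAY and −0.01 with AchA, and p53 targets at 1.34 and 0.86.

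Several lists passed in none of the comparisons. De novo pyrimidine synthesis genes (8) had medians of −0.13 with BAY, 0.26 with AchA and −0.70 with CsnB, 1 rising with BAY (UMPS) and 1 falling (CTPS2, 4.90 FPKM against 9.71 ± 0.563). NME1 and NME2 in that list share sequence and are uncertain. Pyrimidine salvage genes (11) had medians of 0.35, 0.26 and −0.20, TK1 and UCK1 rising with BAY to 206 and 14.6 FPKM. Interferon genes (33) had 5 rising and 1 falling with BAY, ISG15 at 437 FPKM against 124 ± 48.0. Genes of ribosome assembly (47, median 0.13 with BAY), the MYC network (21, 0.41), hypoxia (26, 0.17), ferroptosis (15, 0.17), sugar nucleotides (20, 0.11) and epithelial junctions (17, −0.02) did not pass, nor did fibroblast (4, 0.51) and immune (3, −0.64) markers.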

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

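The test of terminal oligopyrimidine mRNAs as a class, the comparison of vehicle 3 with BAY plus uridine and the list tests of BAY against AchA were chosen after the results were seen. In 7 of 72 genes examined, 1 vehicle lay far from the other 3 by Dixon's ratio, and chance does so for about 1 in 20 groups. In vehicle 1 these were CPA4 (0.52 FPKM), APLP1 (2.21) and TMEM249 (0.91), in vehicle 2 PPP1R10 (24.01), and in vehicle 3 CHAC1 (177.44), INHBE (38.89) and NR4A1 (26.62). NR4A1 in BAY plus uridine (17.2) thus lay below its own vehicle and near the 3 others (15.5, 15 and 15.3).

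Gene lists that differed between BAY and AchA by the test of the difference were ribosomal proteins (median log2 difference −1.64), YAP targets (1.07), immediate early genes (1.04), NF-kB genes (1.02), p53 targets (0.43), Wnt targets (−0.47), fatty acid synthesis genes (−0.46) and oxidative phosphorylation genes (−0.41). None of the 8 did so with an estimated correlation between genes.

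The low ribosomal protein mRNAs of the BAY library might be technical or biological. A bias by transcript length and GC would have brought their median matched ratio near 0 once a fitted trend was removed, and it went from −1.53 to −1.68. Reads shared with pseudogenes would have spared genes with few pseudogenes, and the 37 with fewer than 13.5 had a median of −1.69 against −1.39 in the rest. Other terminal oligopyrimidine mRNAs, which share a growth-controlled start sequence, had −1.47, and the 15 not named for other reasons had −1.37. That list was made when EEF1A1 and EEF1D were already seen to be low, so it describes the fall and does not test it. Library preparation in a single sample could not be tested, and AchA, with the same labelled target, had −0.01 for ribosomal proteins and −0.27 for the other class, with 1 of 18 above 0.

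The low integrated stress response genes of both inhibitor libraries could come from vehicles with a high level, since the list is 0.76 above the other vehicles in vehicle 3. Against each of the 4 vehicles, the median in BAY or AchA was at most −0.86. With median-ratio scaling it was −1.07 in BAY and −1.36 in AchA. Neither the choice of vehicle nor scaling accounts for the fall, while both libraries remain single.

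Vehicle 3 stands apart, and its experiment may differ as a whole, since BAY plus uridine deviates with it (r = 0.90 across genes). Both deviations use the same 3 vehicles, which raises r, and with no vehicle in common it was 0.70 to 0.83. CsnB, from another experiment, had r = 0.55, or 0.38 to 0.54 with none in common, AchA −0.25 and BAY −0.03. Transcript length and GC explained 10.2% of the variance of that deviation, between the bounds set beforehand, so a technical share remains open. A difference of growth between days would fit the raised immediate early genes and lowered S phase genes and was not tested.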

How the results depend on the processing

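Chosen after the results were seen were the model without the experiment of vehicle 3 (2183 genes for the inhibitors, all 966 among them), the list tests of BAY against AchA, those of the inhibitors with a block, the correlation of vehicle 3 with BAY plus uridine (r = 0.90, at lowest 0.70 with no vehicle in common) and the median of other terminal oligopyrimidine mRNAs with BAY. Of 1170 recomputed values for single genes, 1012 kept their side of the threshold, 139 lost a call, 15 gained one and 4 changed sign, none of them a called value. MYC with AchA was −0.034 with quantile normalization and −0.0052 to 0.17 with 1 vehicle left out, and NR4A1 with BAY plus uridine was 0.0077 with median-ratio scaling and −0.10 to 0.16. The cause was not tested for these or for the counts below, except that fewer or more genes or libraries entered. With 1 vehicle left out, genes called ranged from 1054 to 3688 for BAY, 0 to 62 for AchA, 0 to 818 for BAY plus uridine, 0 to 2393 for CsnB, 276 to 2185 for the inhibitors, 562 to 4154 for BAY against BAY plus uridine and 42 to 1787 for BAY against AchA. In each the highest count came without vehicle 3. That vehicle differed most from the others, and leaving it out removes that spread. BAY plus uridine departs from vehicles 1, 2 and 4 as vehicle 3 does (r = 0.90). Its 818 calls without vehicle 3 therefore cannot be told apart from a difference between experiments. A pseudocount of 0.1 gave 10 genes for AchA, 134 for CsnB and 194 for BAY against AchA. No filter (15473 genes) gave 3433 for BAY, 0 for CsnB, 2588 for BAY against BAY plus uridine and 1196 for BAY against AchA, and quantile normalization gave 0 for CsnB. The inhibitors as 1 class gave 77 genes, and with the experiment as a replicate block 46. A block cannot be fitted for single compounds. In the fits with the inhibitors as 1 class, the difference between BAY and AchA counts as spread. Past 2-fold, a pseudocount of 0.1 gave 562 genes for AchA, 94 for BAY plus uridine and 1754 for CsnB, and the mean of the 4 vehicles gave 295 for BAY plus uridine. That mean also gave r = −0.43 for AchA with BAY plus uridine and 0.33 for BAY plus uridine with CsnB. With that mean as reference, BAY plus uridine carries the departure it shares with vehicle 3. The slope of BAY plus uridine on BAY was −0.063 with a pseudocount of 0.1, −0.030 with a mean of at least 5, −0.16 with the mean of the 4 vehicles (same sign 26.7%) and −0.024 for genes past 2-fold with BAY. An estimated correlation left 0 lists in each of the 7 comparisons, 0 of 8 for BAY, 0 of 7 for AchA, 0 of 9 for BAY plus uridine, 0 of 13 for CsnB, 0 of 9 for the inhibitors, 0 of 6 for BAY against BAY plus uridine and 0 of 8 for BAY against AchA. That form of the test rests on 3 residual degrees of freedom, so its counts of 0 do not show that correlation removed the lists. With 1 vehicle left out, lists called ranged from 4 to 9 for AchA and from 5 to 11 for the inhibitors. With the block it was 10 for the inhibitors, 7 of them among the 9, and 0 with an estimated correlation as well. Depth is unknown, so what it limits for low genes is unknown too.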

Other observations

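The lists of PSG genes and of squamous genes were chosen after the results were seen, for genes already known to stand out, so no test of either counts as evidence. The PSG family is a cluster of placental glycoprotein genes on chromosome 19. All 8 measured PSG genes were lower than the own vehicle with CsnB and with BAY plus uridine, with median matched log2 ratios of −0.96 and −1.10, and higher with BAY (1.31) and AchA (1.01). PSG6 went from 2.19 to 17.8 FPKM with BAY and from 1.22 to 0.09 with CsnB. With AchA the ratio leans on a low own vehicle, PSG2 standing at 22 FPKM against 9.25 in vehicle 2 and 15.8 ± 4.63 over the 4 (limma adjusted p = 0.61). CsnB was given without uridine, so the low values of the 2 libraries have no treatment in common. The family shares reads between near-identical copies and counts as close to 1 observation.

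Squamous and cornified genes had a median matched log2 ratio of 1.56 with BAY, 0.50 with AchA and −0.10 with BAY plus uridine. With CsnB it was 0.04, 6 genes being past 2-fold higher and 4 lower. Some were expressed in the vehicles, KLK6 at 9.77 to 31.0 FPKM and KRT17 at 6.72 to 33.9. LCE1E went from 0 to 15.7 FPKM with BAY, COL17A1 from 6.75 to 51.6 and SERPINB2 from 5.96 to 250. SERPINB2 and SPRR2D were also high in vehicle 3 (109 and 57.9 FPKM), where no compound was given.

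NR4A1 rose with BAY and stood at the vehicle level with uridine, while AchA left it at 20.7 FPKM. The p53 targets and integrated stress response genes moved as lists with AchA too at the preset correlation, though not at an estimated one (adjusted p = 0.59 and 0.83). Stress response genes did not differ between BAY and AchA by the test (median log2 difference −0.03, camera adjusted p = 0.51). The p53 targets were 0.43 higher with BAY at the preset correlation (adjusted p = 0.013) and not at an estimated one (adjusted p = 0.97). Whether AchA blocked the pathway less than BAY was not measured, and a dose series of AchA would show whether NR4A1 follows.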
